A study of Mus musculus with 13 samples.

How the data were processed

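RNA was measured in 13 libraries from neurons of the neocortex of mice at postnatal day 10. Per the labels, 3 libraries came from Tomato-positive spiny stellate neurons of layer 4 (SSN) in mice that carried Scnn1a-Cre and a Tomato reporter, 6 from callosal projection neurons of the superficial layers (CPNSL) and 4 from callosal projection neurons of the deep layers (CPNDL). The callosal neurons were labelled in C57Bl/6 wild-type mice by a tracer put into the primary somatosensory cortex of the other hemisphere. Total RNA was extracted with the RNeasy Plus Micro kit and made into libraries with SMARTer and Nextera chemistry, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.11, HTSeq 0.6.1 and the genome build mm10; how the cells were separated, the read layout and whether counting used strand are not given in the sources used here. Library names carry letters (SSN a to c, CPNSL d and e, 5 libraries) or numbers (CPNSL 1 to 4, CPNDL 1 to 4, 8 libraries), here called letter and number libraries, and the labels do not say what the difference marks. Nothing in the labels says whether replicates were separate animals, so p-values measure the spread between these libraries, which may be technical.

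The deposited values, 1 column per library for 9019 genes, are log10 values. They were read, from the values themselves, as log10(CPM + 10), CPM being reads scaled to the library total, moved for each gene by a constant of opposite sign in letter and number libraries so that the mean of the letter and of the number CPNSL libraries is equal. The largest gap between those means was 7.8e-15 on the log10 scale. Undoing this shift gave a whole number of reads, within 0.001, for 117247 of 117247 values (100.0%), and the library totals behind the CPM. For every gene exactly 1 shift met this. Each of the 9019 genes had more than 20 CPM in at least 1 library, and other genes are not analysed here. Of 18 endothelial and mural markers 4 were among them (Col1a1, Col1a2, Dcn and Pdgfrb, none of them endothelial), and of 17 oligodendrocyte lineage markers 6. The absence of a gene was not read as a low level. The recovered totals were 25.4 to 32.0 M reads for SSN, 19.6 to 32.1 M for CPNSL and 14.6 to 19.3 M for CPNDL, and the 9019 genes held 85.4 to 87.6% of them. A limit of 3 reads corresponds to 0.093 to 0.205 CPM, depending on the library, and covers counting error only. Symbols were matched to GENCODE M21 (mm10 coordinates), which gave a position for 8852 and none for 167.

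The test written before the data were examined was a count model. Because the deposited unit is a log10 value, limma 3.58.1 in R 4.3.3 was used instead: the deposited values were multiplied into log2 units and fitted with 1 mean for each of the 4 combinations of group and name series, over all 13 libraries, with an intensity trend in the variance (9 residual degrees of freedom). SSN against CPNSL is then the difference within the letter libraries (3 against 2), CPNSL against CPNDL the difference within the number libraries (4 against 4), and SSN against CPNDL the sum of both, since no name series holds both groups. Letter against number CPNSL libraries were compared on log2(CPM + 10) before the shift. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with calls at an adjusted p under 0.05 and no minimum fold. Changes are on the log2(CPM + 10) scale, which understates the change of genes near or below 10 CPM. For 35 genes all 5 letter libraries held 0 reads; they were left out of the contrasts with SSN, a choice made after seeing the data, which left 8984 genes there and 9019 for CPNSL against CPNDL. Levels are given as mean ± SD of recovered CPM within a name series. CPM of SSN and CPNDL are from different name series and are not comparable, so that comparison is given only as fitted changes.

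The model was tested on simulated values with 200 genes changed by known factors. Of genes changed 2-fold it recovered 83.6% for SSN against CPNSL, 91% for CPNSL against CPNDL and 73.1% for SSN against CPNDL. At 1.5-fold these were 67.2%, 82.1% and 41.8%. False calls were 13 of 176, 11 of 193 and 5 of 144 genes called, in the same order. Genes were simulated independently and all replicates varied alike, which leaves out the closeness of SSN b and c described below.

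Before the data were examined, 23 gene lists and 9 marker lists of other cell types were fixed: markers of layer 4, layer 2/3, layer 5, layer 6 and subplate, and callosal neurons; ephrins, semaphorins, other guidance genes, cadherins, synaptic adhesion genes; glutamate and GABA receptors, potassium channels, sodium, calcium and HCN channels; release machinery, immature neuron and growth cone genes, neurofilament and axon initial segment genes, immediate early genes, stress genes; mitochondrially encoded, nuclear oxidative phosphorylation and ribosomal protein genes, thalamocortical and retinoid-related genes; and markers of GABAergic interneurons, astrocytes, the oligodendrocyte lineage, microglia and macrophages, endothelial and mural cells, erythrocytes, proliferating cells, thalamic relay neurons, and subcerebral and corticothalamic projection neurons. The 30 lists with at least 4 measured members were tested with limma's camera, which compares a list with the other genes under a preset correlation of 0.01, and adjusted over the lists. Camera with a correlation estimated for each list, and fry, were run beside it. For each list the genes called over all genes and those called when p was adjusted over the list alone are counted.

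Named genes followed a rule fixed before the data were examined: in each comparison the 8 called genes with the largest change in each direction, with at least 10 CPM in the higher group, every library of one group above every library of the other and no predicted or clone-based name (for SSN against CPNDL, libraries were ordered on the deposited values); Rorb, Rspo1, Scnn1a, Cux1, Cux2, Lhx2, Bcl11b, Fezf2, Etv1, Tbr1 and Foxp2; and up to 4 members of each list with the smallest p. Rspo1, Scnn1a and Foxp2 are not among the genes analysed here, and part of the other genes that the rule names, most of them list members, are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

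Overlaps of calls between comparisons that share libraries are given beside the overlap of independent lists and the mean of 50 simulated data sets with no group effect, in which as many top-ranked genes were taken as were called. Alternatives fixed before the data were examined were a fit without the name-series term, fits on the libraries of the compared series only, a replicate block, median-of-ratios scaling, voom with quality weights, a stricter filter and leaving out each library. Added after seeing the data were a pseudocount of 1, SSN libraries b and c averaged into 1, the leading residual component as a covariate, genes with a mean of at least 50 CPM, genes at least as high in letter as in number CPNSL libraries, and values without the shift and without the name-series term. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 recovered the reads and drew the plots.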

Results

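The data were log10 expression values per gene from RNA-seq of 13 libraries of neurons that project within the cortex, taken from mouse neocortex at postnatal day 10. SSN were the spiny stellate neurons of layer 4, which receive thalamic input and project locally (3 libraries, a to c). CPNSL and CPNDL were callosal projection neurons, which send an axon to the other hemisphere, of the superficial layers (6 libraries, d, e and 1 to 4) and the deep layers (4 libraries, 1 to 4). Total reads were 28.6, 25.4 and 32.0 M for SSN a to c, 32.1 and 21.6 M for CPNSL d and e, 19.6 to 21.4 M for CPNSL 1 to 4 and 14.6 to 19.3 M for CPNDL 1 to 4. The values covered 9019 genes. SSN came from Scnn1a-Cre reporter mice without a tracer and the callosal neurons from traced wild-type mice, so strain and labelling differed together with the cell type in both comparisons with SSN. The libraries also formed a letter series (SSN a to c, CPNSL d and e) and a number series (CPNSL 1 to 4, CPNDL 1 to 4) that differed in 7027 of 9019 genes within CPNSL, so levels in CPM are set side by side only within a series.

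The comparison of SSN with CPNSL asked how layer 4 neurons with a local axon differ from callosal neurons of the upper layers at the same age. SSN had more transcript of the layer 4 transcription factor Rorb and of several channel and synaptic genes. CPNSL had more transcript of growth cone genes as a list (camera adjusted p = 2.97e-07; adjusted p = 0.383 with an estimated correlation). Met, the receptor for hepatocyte growth factor, was 26.7-fold higher in CPNSL (5.78 ± 2.99 CPM in SSN, SD, n = 3, against 154 ± 40.3 in CPNSL, n = 2). Nptx2, a secreted pentraxin that binds AMPA receptors, was 3.84-fold higher in SSN (144 ± 31.1 against 37.4 ± 22.8 CPM). That ratio was 6.74-fold without CPNSL d and 2.68-fold without CPNSL e.

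Among the genes with the largest rise in SSN were also Kcnab3, an auxiliary subunit of voltage-gated potassium channels (128 ± 24.7 against 32.4 ± 3.83 CPM, log2 change 1.69, SE 0.15), and Kcnip3, which binds Kv4 channels (log2 change 1.54). The other named ones were Zmat4 on the layer 4 list (1.66) and the cholecystokinin receptor Cckbr (1.71, and 1.06 without CPNSL e). With them rose the phospholipase Plch2 (1.54), the calcium channel subunit Cacna2d3 (1.44) and the neurite growth factor neuritin, Nrn1 (1.44). Limma's adjusted p for these 8 genes lay between 5.1e-05 and 0.0048, and that of Nrn1 was 0.092 without CPNSL e. The genes that fell most in SSN were Met (log2 change -3.38, SE 0.25, limma adjusted p = 1.2e-05), the growth-associated tubulin Tubb2b (-3.26) and the insulin-like growth factor binding protein Igfbp4 (-2.92, limma adjusted p = 2e-06). Next came the adhesion protein Mdga1 (-2.78), the secreted protein Nov (-2.42) and the repulsive guidance molecule Rgma (-2.19). With them fell Dpysl3 (-2.61) and Dpysl5 (-2.21), members of the collapsin response mediator family that acts in growth cones. Dpysl5 lost its call without CPNSL e (adjusted p = 0.05). In each of these 16 genes every SSN library lay on one side of both CPNSL libraries, as the naming rule required. The same held for 944 of the 944 called genes. Rorb lies at 18930605 to 19111196 on chromosome 19 (minus strand, mm10), Met at 17463800 to 17573980 on chromosome 6 (plus strand) and Nptx2 at 144545902 to 144557478 on chromosome 5 (plus strand), and all values are for whole genes.

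Layer 4 markers were higher in SSN. Of 7 measured, 2 rose over all genes and 5 when adjusted over the list alone (median log2 change 0.46, camera adjusted p = 0.000101; adjusted p = 0.358 with an estimated correlation). Rorb was at 371 ± 25.5 CPM in SSN and 199 ± 6.2 in CPNSL (log2 change 0.87, limma adjusted p = 0.0029). The thalamocortical and retinoid-related list shares Rorb and Rora with the layer 4 list, and 2 of its 4 members rose, 3 when adjusted over the list alone (median 0.64, camera adjusted p = 0.00107; adjusted p = 0.139 with an estimated correlation). One of them was Cyp26b1, which degrades retinoic acid (27.2 ± 4.94 against 7.62 ± 3.5 CPM, log2 change 1.09). Rora had a log2 difference of 0.40 (limma adjusted p = 0.057). Of 14 layer 2/3 markers, 4 fell and 0 rose in SSN, or 5 fell and 1 rose when adjusted over the list alone (median -0.44, camera adjusted p = 0.0469; adjusted p = 0.522 with an estimated correlation). They included Wfs1 (-1.71) and the cadherin Cdh13 (-1.29). Without SSN b or c, CPNSL d, 1 or 2, or CPNDL 3 or 4, the adjusted p of this list was 0.0503 to 0.0858. It was 0.0737 without the name-series term, 0.0886 with the replicate block, 0.107 with a pseudocount of 1 and 0.0511 with SSN b and c averaged. Of 12 layer 5 markers 5 fell, also when adjusted over the list alone, among them Parm1 (-1.53) and the contactin Cntn6 (-0.79) (median -0.24, camera adjusted p = 0.0469; adjusted p = 0.358 with an estimated correlation). The layer 5 list lost its call without SSN b, CPNSL 1 or 2, or CPNDL 1, 2 or 3 (adjusted p 0.0503 to 0.0683). It also lost it without the name-series term (0.0737), with a pseudocount of 1 (0.0825) and with SSN b and c averaged (0.0502).

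The layer 6 and subplate list did not pass (camera adjusted p = 0.0631), with a rise of Col5a1 (0.98) and Ppp1r1b (1.24) and a fall of the transcription factor Sox5 (-0.94). Callosal markers went both ways and did not pass (camera adjusted p = 0.656, a positive direction against a median of -0.07 and a mean of -0.06). The calcium-binding copine Cpne4 fell (2.72 ± 0.535 against 47.3 ± 12.7 CPM, log2 change -2.15, limma adjusted p = 9e-06), as did Tmtc4 (-0.75), and the neurturin receptor Gfra2 rose (0.98, or 0.64 without CPNSL e). Subcerebral and corticothalamic markers (adjusted p = 0.669) and thalamic relay markers (0.304) did not pass camera's test, although fry called the thalamic list (0.0036). Among single transcription factors of cortical identity, Cux1 (0.35), Cux2 (0.49), Lhx2 (-0.63), Bcl11b (0.02), Fezf2 (-0.32) and Tbr1 (0.53) gave limma adjusted p of 0.18 to 0.98. Etv1 of layer 5 had a log2 change of -0.62 (limma adjusted p = 0.026), and its adjusted p was 0.052 without SSN a, 0.085 without SSN b and 0.073 without SSN c. The change of Etv1 was -0.26 without CPNSL e (adjusted p = 0.31) and -0.98 without CPNSL d.

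Genes of immature neurons and growth cones fell together in SSN. Of 24 measured, 15 fell and 0 rose, or 16 and 1 when adjusted over the list alone (median -0.55, camera adjusted p = 2.97e-07; adjusted p = 0.383 with an estimated correlation). Gap43, a major growth cone protein, was at 157 ± 51.3 CPM in SSN and 541 ± 124 in CPNSL (log2 change -1.75, limma adjusted p = 0.00034). The tubulin-binding stathmin Stmn2 was at 815 ± 61.7 against 1561 ± 222 CPM (-0.92). The SSN libraries were unequal in some of these genes, with Tubb2b at 40.3, 5.67 and 7.09 CPM in SSN a, b and c and at 145 and 328 in CPNSL d and e. The neurofilament light and medium chains fell as well, Nefl by 1.49 and Nefm by 0.89 on the log2 scale, although their list of 14 as a whole did not pass (3 fell, camera adjusted p = 0.115; by fry 0.00692). Guidance and adhesion lists did not pass camera either. Among them were semaphorins and plexins (5 of 25 fell and 1 rose, adjusted p = 0.304) and the Slit, Robo, netrin and Wnt list (6 of 19 fell, 0.302; by fry 0.0373). The other ones were cadherins (10 of 23 fell and 1 rose, 0.0741, by fry 0.0373), synaptic adhesion genes (10 of 43 fell, 0.061, by fry 0.037) and ephrins (1 of 14 fell and 1 rose, 0.914, with a median of 0.00 and a mean of -0.12 against a positive test). Their members with the smallest p included the semaphorin receptor Plxnc1 (-0.97), Slit3 (-1.20), the protocadherin Pcdh19 (-1.59), Lrrtm4 (-1.71) and Lrrtm3 (-1.56), which are leucine-rich repeat proteins of the postsynaptic membrane, Efnb3 (-1.65) and Efna5 (0.61).

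**Figure D1:**
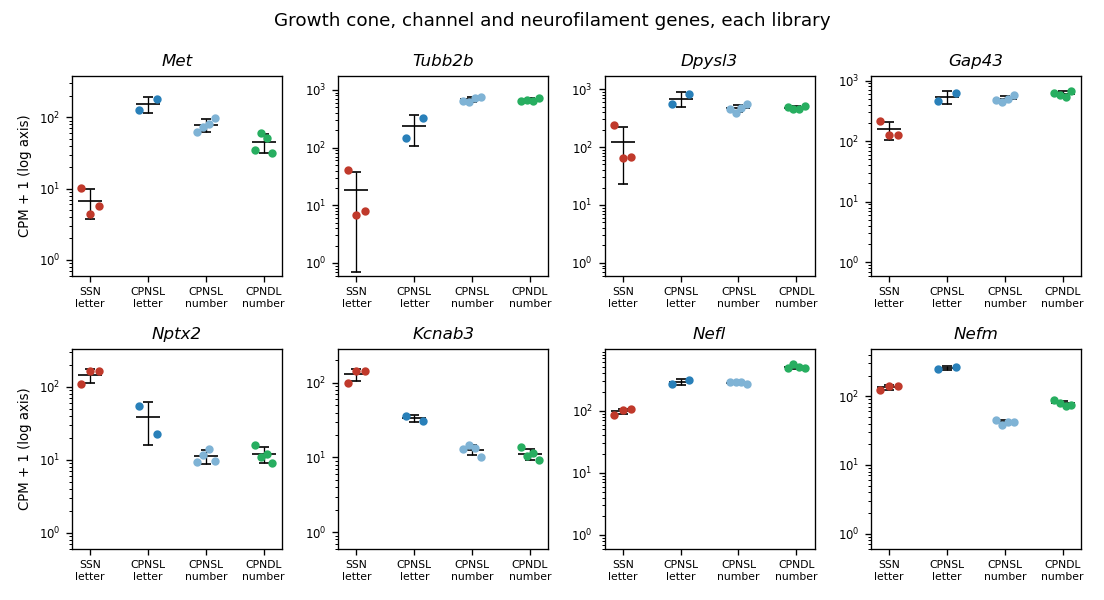
Each dot is 1 library, as CPM plus 1 on a log axis, for SSN and CPNSL of the letter series and CPNSL and CPNDL of the number series; black marks show the mean and SD, and bars end at the foot of the axis where the mean minus the SD lies below it. Met was at 5.78 CPM in SSN and 154 in CPNSL of the same series, and Kcnab3 at 128 and 32.4.

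Potassium channel genes were higher in SSN on balance. Of 44 measured, 9 rose and 4 fell, or 12 and 6 when adjusted over the list alone (median 0.14, camera adjusted p = 0.00443; adjusted p = 0.611 with an estimated correlation, 0.248 by fry and 0.073 without CPNSL e). Kcng1, a modulatory subunit of Kv2 channels, and the beta subunit Kcnab1 were among those that fell (-1.76 and -0.86). Genes of synaptic vesicles and release rose, 7 of 32 with 1 that fell, or 11 and 1 when adjusted over the list alone (median 0.24, camera adjusted p = 2.6e-05; adjusted p = 0.375 with an estimated correlation and 0.0531 by fry). The vesicular glutamate transporter Slc17a7 was at 2453 ± 252 CPM in SSN and 1766 ± 188 in CPNSL (log2 change 0.47, limma adjusted p = 0.02, and 0.086, 0.082 and 0.26 without SSN b, SSN c and CPNSL e), and the vesicle protein Sv2c fell (-0.95). GABA receptor genes changed subunit by subunit. Gabra5 (38.5 ± 11.7 against 133 ± 4.11 CPM, log2 change -1.59), Gabrg3 (-1.63) and Gabra3 (-1.06) fell. Gabrd, the delta subunit of extrasynaptic receptors, rose (159 ± 17.4 against 70.8 ± 18.5 CPM, log2 change 1.08). The list as a whole did not pass (3 of 16 rose and 3 fell, camera adjusted p = 0.96). Glutamate receptors did not pass either (2 of 25 rose and 4 fell, 0.656, with a median of 0.02, a mean of -0.02 and a positive test), with a fall of the AMPA receptor subunit Gria3 (-1.22) and a rise of the metabotropic receptor Grm2 (1.03). Sodium, calcium and HCN channels did not pass (3 of 27 rose and 6 fell, 0.96), with falls of Scn3b (-0.99) and Hcn3 (-1.04).

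Immediate early genes were higher in SSN as a list (2 of 17 rose, also when adjusted over the list alone, median 0.22, camera adjusted p = 0.0103; adjusted p = 0.769 with an estimated correlation and 0.294 by fry). That call was lost without SSN b (0.0503), without CPNSL e (0.242) and with median-of-ratios scaling (0.0505). Nptx2 was 1 of the 2, and the other was Ier5 (1.24, limma adjusted p = 0.029, and 0.099, 0.095 and 0.35 without SSN b, SSN c and CPNSL e). Of 8 mitochondrially encoded genes 0 were called over all genes and 5 fell when adjusted over the list alone (median -0.28, camera adjusted p = 0.0304, 0.0503 without SSN b and 0.0539 with a pseudocount of 1; adjusted p = 0.769 with an estimated correlation and 0.098 by fry). Cytosolic ribosomal protein genes had a median of -0.15, with 1 of 76 lower and 0 when adjusted over the list alone (camera adjusted p = 0.00223, 0.0537 without SSN a; adjusted p = 0.882 with an estimated correlation and 0.28 by fry). Nuclear oxidative phosphorylation genes (0 of 65 called, adjusted p = 0.656, median -0.02 and a positive test) and stress genes (1 of 9 fell, 0.487) did not pass camera's test. Of markers of other cells, those of microglia and macrophages were lower in SSN (1 of 15 fell, 6 when adjusted over the list alone, median -0.68, camera adjusted p = 0.00426; adjusted p = 0.769 with an estimated correlation and 0.148 by fry). Csf1r, the receptor that microglia depend on, was at 4.08 ± 1.78 against 24.5 ± 10.2 CPM, but limma's adjusted p of 0.034 was 0.11, 0.10 and 0.34 without SSN b, SSN c and CPNSL e. Lists of interneurons (1 of 10 fell, adjusted p = 0.909) and astrocytes (2 of 14 fell, 0.656) did not pass. The oligodendrocyte lineage (0 of 6, 0.946, median -0.06 and a positive test) and endothelial and mural cells (0 of 4, 0.762, median -0.02 and a positive test) did not pass camera's test.

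In all, 944 of 8984 genes differed between SSN and CPNSL, 298 higher and 646 lower in SSN, with at least a 2-fold change in 26 and 111 of them. With median-of-ratios scaling the split was 475 higher and 468 lower of 943. The count fell to 495 without SSN b and 511 without SSN c. It fell furthest without CPNSL e and less without CPNSL d, although either leaves 1 CPNSL library in the letter series. SSN b and c were far closer to each other than other replicates, and with them averaged into 1 library the count was 506. Averaging also leaves 1 library fewer. So does leaving out SSN a, which keeps b and c as 2 libraries, and the count was then 985. This argues against the number of libraries alone as the cause of the fall to 506.

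**Figure D2:**
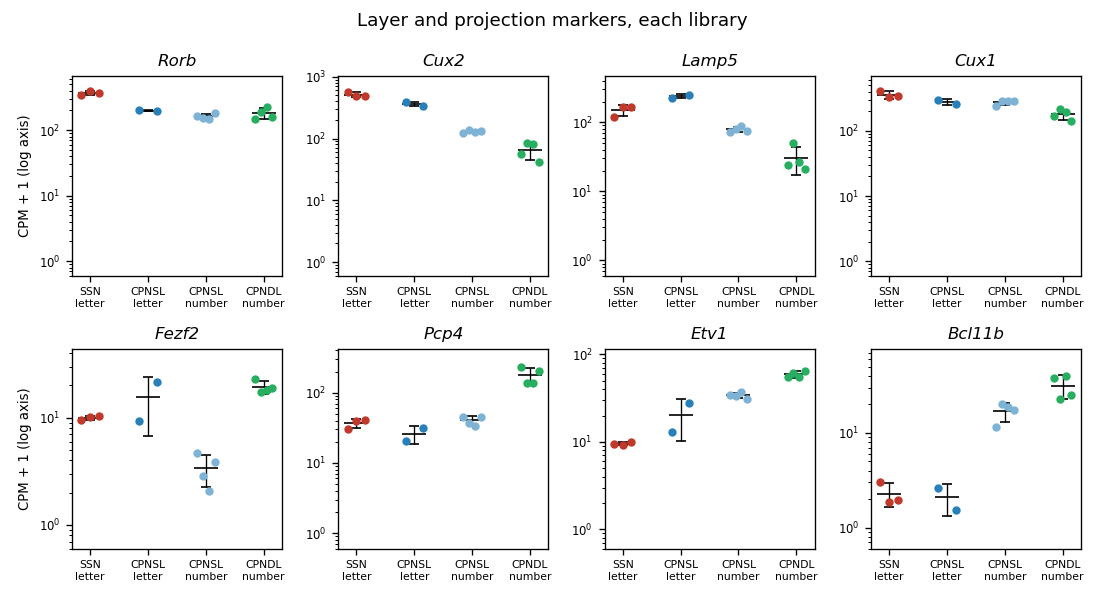
Each dot is 1 library, as CPM plus 1 on a log axis, for SSN and CPNSL of the letter series and CPNSL and CPNDL of the number series; black marks show the mean and SD. Rorb was at 371 CPM in SSN and 199 in CPNSL of the same series, and Fezf2 at 2.37 CPM in CPNSL and 18.3 in CPNDL of the number series.

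The comparison of CPNSL with CPNDL asked how callosal neurons differ by layer. By camera, superficial libraries had more transcript of layer 2/3 markers (adjusted p = 0.0611 with an estimated correlation) and of synaptic adhesion genes (0.273). Deep libraries had more of layer 5 markers (0.0434 with an estimated correlation), layer 6 and subplate markers (0.141) and subcerebral and corticothalamic markers (0.0616). All of these are number libraries, in which markers of other cells were high. Whether RNA of other neurons than the labelled ones enters these lists was not tested. The calmodulin-binding protein Pcp4 was 4.5-fold higher in CPNDL (39.4 ± 5.7 CPM in CPNSL against 177 ± 47.3 in CPNDL, SD, n = 4 each). Fezf2, a transcription factor that specifies subcerebral neurons, was 7.72-fold higher in CPNDL (2.37 ± 1.13 against 18.3 ± 2.56 CPM), and Nov was 3.08-fold higher in CPNSL (174 ± 13.7 against 56.6 ± 8.91 CPM). The collagens Col1a1 and Col1a2 were higher in the superficial libraries, and oligodendrocyte lineage markers in the deep libraries (camera adjusted p = 3.67e-05; adjusted p = 0.133 with an estimated correlation).

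Of 14 layer 2/3 markers 6 were higher in CPNSL, 9 when adjusted over the list alone (median 0.50, camera adjusted p = 3.51e-06; adjusted p = 0.0611 with an estimated correlation). They included the transcription factors Cux2 (129 ± 5.34 against 64.9 ± 20.4 CPM, log2 change 0.93) and Pou3f2 (0.49), the membrane protein Lamp5 (1.21) and calbindin, Calb1 (0.79), with limma adjusted p of 0.00087 to 0.007. Of 12 layer 5 markers 5 were lower in CPNSL, or 6 lower and 2 higher when adjusted over the list alone (median -0.37, camera adjusted p = 4.41e-05, and 0.0434 with an estimated correlation). Pcp4 (-1.90, SE 0.17, limma adjusted p = 0.00036), Fezf2 (-1.20), Etv1 (-0.67) and the transcriptional cofactor Ldb2 (-0.70) were among the 5. Layer 6 and subplate markers were lower in 4 of 10, 5 when adjusted over the list alone (median -0.68, camera adjusted p = 6.63e-07; adjusted p = 0.141 with an estimated correlation). These were the nuclear receptor Nr4a2 (2.95 ± 0.438 against 26.4 ± 9.65 CPM, -1.45), the synaptotagmin Syt6 (-1.32), the heparan sulfate enzyme Hs3st4 (-1.24) and Rprm (-1.03). Subcerebral and corticothalamic markers, which share members with both lists, were lower in 6 of 10, 7 when adjusted over the list alone (median -0.67, camera adjusted p = 3.09e-12; adjusted p = 0.0616 with an estimated correlation). Hs3st2, an enzyme related to Hs3st4, was also among the genes with the largest change (-1.46, limma adjusted p = 0.00018). Cux1 (0.58) was called as higher in CPNSL and Bcl11b (-0.63) as higher in CPNDL, with limma adjusted p of 0.017 and 0.033. Cux1 lost its call without CPNSL 3, CPNSL 4 or CPNDL 1 (0.057 to 0.059) and Bcl11b without SSN b or c, CPNSL 1, 3 or 4, or CPNDL 1 or 3 (0.052 to 0.10). Rorb (-0.14), Lhx2 (-0.02) and Tbr1 (-0.49) gave limma adjusted p of 0.62, 0.98 and 0.59. Layer 4 markers did not pass (0 of 7 called, camera adjusted p = 0.713, median -0.13, mean 0.00), nor did callosal markers (3 of 15 higher and 2 lower, 0.403), of which the Rac regulator Chn2 was lower (-0.94).

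Synaptic adhesion genes were higher in CPNSL in 6 of 43 and lower in 0, or 14 and 0 when adjusted over the list alone (median 0.23, camera adjusted p = 2.21e-06; adjusted p = 0.273 with an estimated correlation). Cntnap2, a neurexin-related protein, was at 45.0 ± 3.14 CPM in CPNSL and 22.4 ± 3.23 in CPNDL (log2 change 0.77, limma adjusted p = 0.00076), and Lrrtm4 (0.80) and Lrrtm3 (0.59) were higher as well. Sodium, calcium and HCN channels were higher in 3 of 27, or 7 higher and 1 lower when adjusted over the list alone (median 0.18, camera adjusted p = 0.00894; adjusted p = 0.425 with an estimated correlation), among them the calcium channel subunit Cacna2d1 (0.62). GABA receptors were higher in 3 of 16, 9 when adjusted over the list alone (median 0.29, camera adjusted p = 0.0409; adjusted p = 0.273 with an estimated correlation). That list lost its call without SSN a, CPNSL 1, 3 or 4, or CPNDL 2 (0.0502 to 0.091). The same happened with the replicate block (0.0628) and with the residual component as a covariate (0.0561). Glutamate receptors did not pass (6 of 25 higher and 1 lower, camera adjusted p = 0.147), although Cacng3, an auxiliary subunit of AMPA receptors (0.97), and Gria2 (0.38) were higher and Grm2 was lower (-0.57). Neurofilament and axon initial segment genes were lower in CPNSL in 3 of 14, or 5 lower and 1 higher when adjusted over the list alone (median -0.05, mean -0.15, camera adjusted p = 0.0253; adjusted p = 0.332 with an estimated correlation). Nefl was at 281 ± 9.74 CPM in CPNSL and 511 ± 34.7 in CPNDL (log2 change -0.84) and Nefm at 41.1 ± 2.78 and 77.7 ± 7.28 (-0.78). The call of the neurofilament list was lost without CPNSL 1 (0.0854), CPNSL 3 (0.0547) or CPNDL 3 (0.102). Synaptic adhesion genes, sodium, calcium and HCN channels and GABA receptors were lower in number than in letter CPNSL libraries (medians -1.07, -1.77 and -1.09). So were release genes (-1.35), layer 4 markers (-1.35) and neurofilament genes (-1.02), which were not called as lists higher in CPNSL here. Whether a different share of neuronal RNA in CPNSL and CPNDL contributed was not settled.

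Other neuronal lists did not pass camera's test in this comparison. They were potassium channels (3 of 44 higher and 2 lower, adjusted p = 0.141), release genes (1 of 32 higher and 4 lower, 0.11) and semaphorins (2 of 25 higher and 3 lower, 0.514). The same held for ephrins (1 of 14 higher and 1 lower, 0.203), the Slit and Wnt list (0 of 19, 0.399), cadherins (0 of 23, 0.203) and immature neuron genes (0 of 24, 0.891). Single members that changed were the leak channel Kcnk2 (-0.65), Kcnab1 (-0.53), Kcnf1 (0.66), the release regulator Cplx1 (-0.52), Slc17a7 (-0.43), Syn3 (0.57), Sema3a (0.74), Sema7a (0.57), Sema4d (-0.66) and the semaphorin receptor Plxnb3 (-1.23), with limma adjusted p of 0.00036 to 0.015. The call of Slc17a7 was lost without CPNDL 1 (0.05). Immediate early genes (0 of 17, adjusted p = 0.407), stress genes (0 of 9, 0.765) and mitochondrially encoded genes (0 of 13, 0.346) were not called by camera. Nor were nuclear oxidative phosphorylation genes (0 of 65, 0.329), ribosomal protein genes (0 of 76, 0.141) and the thalamocortical list (0 of 4, 0.399).

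Markers of non-neuronal cells differed in both directions. Of 18 endothelial and mural markers listed, 4 were measured, and 3 of them were higher in CPNSL, also when adjusted over the list alone (median 1.52, camera adjusted p = 7.45e-06; adjusted p = 0.0616 with an estimated correlation). They were the fibroblast collagens Col1a1 (60.7 ± 16.2 against 4.85 ± 6.31 CPM, log2 change 2.31) and Col1a2 (1.58) and the proteoglycan Dcn (1.46), while the pericyte receptor Pdgfrb differed by 0.05. Single macrophage genes were also among the largest changes: the transglutaminase F13a1 (2.3), the chemokine Pf4 (1.45), Lyve1 (1.35) and the mannose receptor Mrc1 (1.40). Limma's adjusted p of Mrc1 was 0.045, and 0.05 to 0.14 without SSN a, b or c, CPNSL 2, 3 or 4, or CPNDL 1, 3 or 4. The microglia and macrophage list did not pass (1 of 15 higher, camera adjusted p = 0.329). Oligodendrocyte lineage markers were lower in CPNSL in 3 of 6, 4 when adjusted over the list alone (median -0.54, camera adjusted p = 3.67e-05; adjusted p = 0.133 with an estimated correlation), with Enpp6 at 7.63 ± 3.88 CPM in CPNSL and 63.8 ± 31.9 in CPNDL (-1.99). The myelin lipid enzyme Ugt8a (-1.80), Adamts4 (-1.56) and Bcas1 (-1.34), all found in cells forming myelin, fell with it. Astrocyte markers were lower in 1 of 14, 3 when adjusted over the list alone (median -0.17, camera adjusted p = 0.00799, 0.0502 without CPNSL 4; adjusted p = 0.502 with an estimated correlation and 0.207 by fry), with Ntsr2 at -0.73. Interneuron markers did not pass (2 of 10 higher, camera adjusted p = 0.611), with the neuropeptide Vip at 18.5 ± 4.86 against 7.04 ± 0.743 CPM (0.73) and Dlx1 at 0.42 (limma adjusted p = 0.015, 0.053 without CPNSL 4). Thalamic relay markers did not pass (1 of 5 lower, camera adjusted p = 0.203; by fry 0.00966).

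In all, 429 of 9019 genes differed between CPNSL and CPNDL, 279 higher and 150 lower in CPNSL. The change was at least 2-fold in 15 and 19 of them. With median-of-ratios scaling the split was 233 higher and 182 lower of 415. The count of 429 fell to 233 without CPNSL 3, 240 without CPNSL 4 and 258 without CPNDL 1. It also depended on libraries outside this comparison, because all libraries shared 1 estimate of the spread. It was 316 without SSN b, 307 without SSN c and 315 with SSN b and c averaged. With only the number libraries in the fit it was 219.

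The comparison of SSN with CPNDL set layer 4 neurons against callosal neurons of the deep layers. No name series held both groups. Each change is therefore the sum of the change from SSN to CPNSL among letter libraries and from CPNSL to CPNDL among number libraries. The non-neuronal difference among the number libraries enters this sum, and whether RNA of other neurons there does was not tested. By camera, SSN had more transcript of layer 4 markers and potassium channel genes (adjusted p = 0.318 each with an estimated correlation). They had less of layer 5 markers (0.00935 with an estimated correlation), subcerebral and corticothalamic markers (0.239) and growth cone genes (0.318). Nefl fell by 2.33 on the log2 scale (SE 0.13, limma adjusted p = 3.4e-06), and Kcnab3 rose by 1.79 (SE 0.19, limma adjusted p = 0.0004). Both changes rest on 3 SSN, 2 letter CPNSL, 4 number CPNSL and 4 CPNDL libraries.

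The other genes with the largest rise in SSN were the extracellular matrix proteins Ccdc80 (1.88) and Col6a1 (1.76), Nell1 (1.68), Kcnip3 (1.57), Zmat4 (1.53), Nptx2 (1.71) and Cux2 (1.43), with limma adjusted p of 0.00021 to 0.01. Without CPNSL e, Nptx2 had 0.052 and Cux2 0.071. The genes that fell most were Tubb2b (-3.24), Met (-2.65), Dpysl3 (-2.64), Nefl, Cpne4 (-2.25), the surface glycoprotein Cd24a (-2.15), Igfbp4 (-2.07) and Gap43 (-2.03), and of these Dpysl3 (0.093) and Cd24a (0.065) lost their calls without CPNSL e. Layer 4 markers rose in 3 of 7, also when adjusted over the list alone (median 0.62, camera adjusted p = 0.000546; adjusted p = 0.318 with an estimated correlation). Rorb had a log2 change of 0.73 (limma adjusted p = 0.041), which was lost without any of SSN b or c, CPNSL d, e or 1 to 4, or CPNDL 1 or 4 (0.055 to 0.20). Layer 5 markers fell in 6 of 12, 9 when adjusted over the list alone (median -0.83, camera adjusted p = 6.42e-07, and 0.00935 with an estimated correlation), with Fezf2 at -1.51, Etv1 at -1.28, Parm1 at -1.24 and Ldb2 at -0.85. Subcerebral and corticothalamic markers fell in 5 of 10, 8 when adjusted over the list alone (median -0.93, camera adjusted p = 6.42e-07; adjusted p = 0.239 with an estimated correlation), among them Sox5 (-1.08) and S100a10 (-1.0). The thalamocortical list rose in 2 of 4, also when adjusted over the list alone (median 0.44, camera adjusted p = 0.00542; adjusted p = 0.17 with an estimated correlation), with Cyp26b1 at 1.01. Layer 2/3 markers (3 of 14 rose and 3 fell, adjusted p = 0.442, median 0.06, mean -0.05), layer 6 markers (2 of 10 rose and 2 fell, 0.139) and callosal markers (2 of 15 rose and 1 fell, 0.362) did not pass camera's test. Cux1 rose (0.93, limma adjusted p = 0.018, 0.13 without CPNSL e), and Lhx2 (-0.66), Bcl11b (-0.61) and Tbr1 (0.04) gave limma adjusted p of 0.19 to 0.99.

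Immature neuron and growth cone genes fell in 10 of 24, or 11 with 1 that rose when adjusted over the list alone (median -0.62, camera adjusted p = 9.48e-07; adjusted p = 0.318 with an estimated correlation). Neurofilament genes fell in 3 of 14, 4 when adjusted over the list alone (median -0.07, mean -0.42, camera adjusted p = 0.0187; adjusted p = 0.318 with an estimated correlation), and Nefm fell by 1.67. The neurofilament list lost its call without CPNSL d (0.0629) or CPNSL 1 (0.0518) and without the name-series term (0.055). Potassium channels rose in 7 of 44 and fell in 4, or 13 and 5 when adjusted over the list alone (median 0.22, camera adjusted p = 0.00072; adjusted p = 0.318 with an estimated correlation and 0.139 by fry), with Kcns1 at 1.06 and Kcnab1 at -1.39. Release genes had 1 higher and 2 lower of 32, also when adjusted over the list alone (median 0.17, camera adjusted p = 0.0112, 0.129 without CPNSL e; adjusted p = 0.551 with an estimated correlation and 0.312 by fry), and Sv2c fell (-0.79). GABA receptors did not pass (4 of 16 rose and 3 fell, camera adjusted p = 0.418, median 0.06, mean -0.06), with Gabra5 at -1.83, Gabrg3 at -1.25 and Gabrd at 1.09. Camera also gave no call for glutamate receptors (2 of 25 rose and 3 fell, 0.0844), sodium, calcium and HCN channels (3 of 27 rose and 2 fell, 0.178) and ephrins (1 of 14 rose, 0.348). It gave none for semaphorins (2 of 25 rose and 5 fell, 0.444), the Slit and Wnt list (2 of 19 rose and 4 fell, 0.395), cadherins (1 of 23 rose and 4 fell, 0.247) and synaptic adhesion genes (1 of 43 rose and 6 fell, 0.444, median 0.07, mean 0.00). Rgma (-2.0), Pcdh19 (-1.61), the teneurin Tenm1 (-1.24) and Cntnap5b (-0.99) were among the members that fell.

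Among markers of other cells, 3 of 4 endothelial and mural genes were higher in SSN, also when adjusted over the list alone (median 1.5, camera adjusted p = 0.000198; adjusted p = 0.17 with an estimated correlation), and these were Col1a1 (2.25), Col1a2 (1.56) and Dcn (1.43). Col1a1 was at 1.49 ± 0.675 CPM in SSN and 1.94 ± 0.854 in CPNSL of the letter series, so its change comes from the number libraries, and the same holds for Col1a2 and Dcn, which differed by -0.02 each between SSN and CPNSL. Oligodendrocyte lineage markers were lower in SSN in 1 of 6, 3 when adjusted over the list alone (median -0.60, camera adjusted p = 0.0112, 0.103 without CPNSL d; adjusted p = 0.325 with an estimated correlation). Microglial markers had 0 of 15 called and 3 lower when adjusted over the list alone (median -0.77, camera adjusted p = 0.00229; adjusted p = 0.679 with an estimated correlation and 0.288 by fry). Astrocyte markers were lower in 2 of 14, 3 when adjusted over the list alone (median -0.30, camera adjusted p = 0.0225; adjusted p = 0.617 with an estimated correlation and 0.184 by fry), a call lost without SSN b (0.0524), CPNSL d (0.404) or CPNSL 4 (0.0607). Mitochondrially encoded genes had 0 of 8 called, also when adjusted over the list alone (median -0.33, camera adjusted p = 0.0168, 0.0517 without CPNDL 4; adjusted p = 0.617 with an estimated correlation and 0.206 by fry). Lists not called by camera were immediate early genes (1 of 17 rose, adjusted p = 0.0675), stress genes (0 of 9, 0.458), nuclear oxidative phosphorylation genes (0 of 65, 0.904), ribosomal protein genes (0 of 76, 0.0844), interneurons (1 of 10 fell, 0.656) and thalamic relay neurons (2 of 5 fell, 0.0844; by fry 0.0016). Of the erythrocyte list 0 genes were measured, and the 3 measured genes of proliferating cells were too few to test (medians -0.06, -0.13 and -0.13 in the 3 comparisons in the order given).

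In all, 542 of 8984 genes differed between SSN and CPNDL, 205 higher and 337 lower in SSN, with at least a 2-fold change in 37 and 97 of them. With median-of-ratios scaling the split was 284 higher and 279 lower of 563. The count fell to 255 without SSN b, 270 without SSN c and 148 without CPNSL e, and to 262 with SSN b and c averaged.

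**Figure D3:**
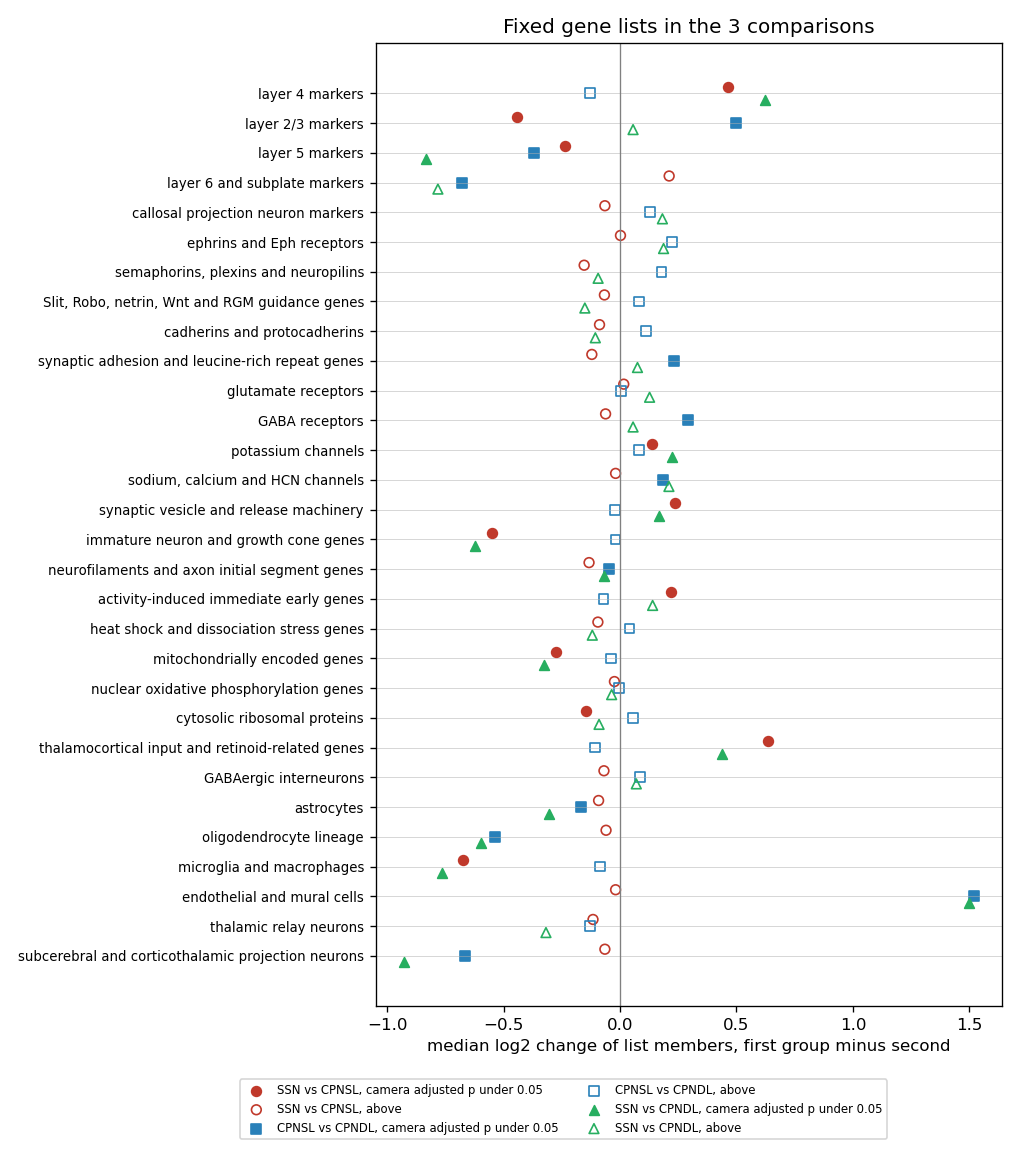
Each symbol is the median log2 change of the measured members of 1 fixed list in 1 comparison, first group minus second, and filled symbols mark a camera adjusted p under 0.05. Growth cone genes had medians of -0.55 and -0.62 in the comparisons of SSN with CPNSL and with CPNDL, and layer 5 markers were below 0 in all 3 comparisons.

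SSN differed from both callosal groups in the same direction in 401 genes, 136 higher and 265 lower, and in opposite directions in 0. Independent lists of these sizes would share 31 genes, and data simulated with no group effect, in which both comparisons use the same SSN and CPNSL libraries, gave 340 on average. The genes that moved the same way included Kcnab3, Kcnip3, Zmat4 and Gabrd, which were higher in SSN, and Met, Igfbp4, Gap43, Nefl and Gabra5, which were lower. That count fell to 192 without SSN b, 197 without SSN c and 111 without CPNSL e. CPNDL differed from SSN and from CPNSL in the same direction in 116 genes, against 12 for independent lists and 144 in the simulations, and in opposite directions in 16. That count fell to 57 without SSN b, 56 without SSN c, 67 without CPNSL d, 38 without CPNSL e, 56 without CPNSL 3 and 67 without CPNSL 4.

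The comparisons of SSN with CPNSL and of CPNSL with CPNDL used different libraries, and 139 genes were called in both (odds ratio 4.61, Fisher's exact test, two-sided, p = 4.5e-37). Fisher's test takes the lists as independent, but 1 fit with shared gene variances gave both. Data simulated with no group effect gave 36.2 genes called in the same direction and 36.7 in opposite directions on average, against 29 and 110 here. In 91 of them CPNSL was above both other groups (20.1 for independent lists) and in 19 below both (4.98). In 10 the order was SSN, CPNSL, CPNDL from high to low (9.25), and in 19 from low to high (10.8). Together these 29 lie below the simulated 36.2. Genes highest in CPNSL included Nov, Lrrtm3, Lrrtm4 and Tmtc4, of which Tmtc4 had a limma adjusted p of 0.05 between CPNSL and CPNDL without CPNSL 4. Grm2 was among the genes lowest in CPNSL. Nefl, Nefm and Kcnab1 were lowest in SSN and highest in CPNDL. Across genes, which are not independent replicates, the 2 sets of log2 changes had a correlation of -0.17.

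Within CPNSL the letter libraries (n = 2) differed from the number libraries (n = 4) in 7027 of 9019 genes, 3598 higher and 3429 lower in letter libraries, before the shift that makes the means of these libraries equal. Markers of other cells were higher in number libraries. The median log2 difference was 4.10 for 14 astrocyte genes, 3.19 for 6 oligodendrocyte lineage genes and 3.56 for 15 microglial and macrophage genes. It was 2.10 for the 4 measured genes of the endothelial and mural list, Col1a1, Col1a2, Dcn and Pdgfrb. Apoe, an abundant astrocyte transcript, was at 80.6 ± 0.106 CPM in letter and 4940 ± 777 in number CPNSL libraries, and Olig1, of the oligodendrocyte lineage, at 5.81 ± 4.03 and 476 ± 30.0. Release genes (median -1.35) and sodium, calcium and HCN channels (-1.77) were lower in number libraries, with Syt1, the calcium sensor of release, at 1740 ± 58.0 CPM in letter and 471 ± 39.4 in number libraries. Layer 4 (median -1.35) and layer 2/3 markers (-1.26), ephrins (-1.30), glutamate (-1.14) and GABA receptors (-1.09), potassium channels (-1.09), synaptic adhesion genes (-1.07) and neurofilament genes (-1.02) were lower too. Medians near or above 0 were found for layer 6 and subplate markers (-0.02), semaphorins (0.18), subcerebral and corticothalamic markers (0.35) and interneurons (1.42). Nuclear oxidative phosphorylation genes were higher in number libraries in 65 of 65, with a median of 1.35, and mitochondrially encoded genes in 8 of 8, with a median of 1.36, leaving out 5 genes listed at 0 reads in all 5 letter libraries. The letter and number CPNDL or SSN libraries cannot be compared, because each of these groups lay in 1 series.

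**Figure D4:**
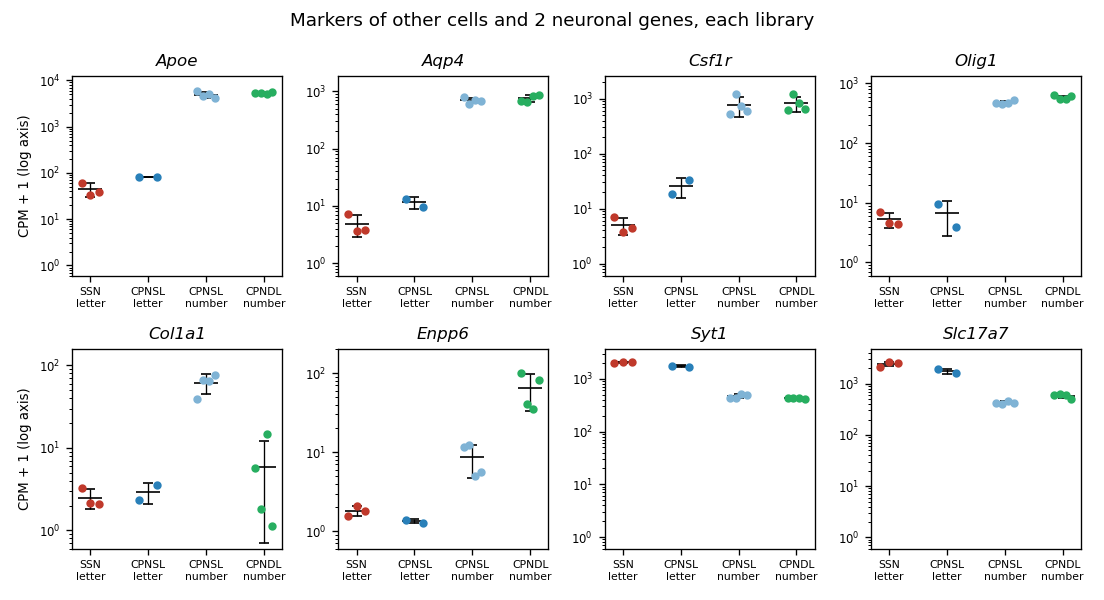
Each dot is 1 library, as CPM plus 1 on a log axis, for SSN and CPNSL of the letter series and CPNSL and CPNDL of the number series; black marks show the mean and SD, and bars end at the foot of the axis where the mean minus the SD lies below it. Apoe was at 80.6 CPM in letter and 4940 in number CPNSL libraries, and Col1a1 at 60.7 in CPNSL and 4.85 in CPNDL of the number series.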

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

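All tests in this part were chosen after the results they concern had been seen.

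Each of 452 sets of 4 or 6 libraries of 1 group, made of total reads or of the deposited values of a named gene, was examined for a library far from the others, by its gap to the nearest library divided by the range of the set. Chance alone marks about 1 in 20 sets, or 22.6 here, and 20 were found. Among CPNSL they were total reads in library d (0.838, with 32.1 M reads), Fez1 (0.647), Sema3a (0.702) and Sema4d (0.638) in library 2, Plxnb3 in library 3 (0.677) and mt-Atp6 in library 1 (0.628). In CPNDL they were Ccdc80 (0.926) and Gabra4 (0.955) in library 1, Gria3 (0.884), Igfbp4 (0.87), Lyve1 (0.899) and Nrn1 (0.865) in library 2, Atf4 (0.93), Col1a2 (0.846), Cyc1 (0.854), Pcdh11x (0.901) and Robo1 (0.925) in library 3, and Cspg4 (0.899), Rps12 (0.99) and mt-Nd2 (0.862) in library 4.

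Letter and number CPNSL libraries differed in 7027 genes although the labels give them 1 cell type, so no biological explanation was tested. Dilution of neuronal RNA by 1 factor as the whole cause was not settled by the spread of release genes. The middle 80% of the 32 genes spanned 2.01 on the log2 scale (-2.08 to -0.07), 17.4 times their median SE of 0.12. This scale understates the change of genes at low levels, so 1 factor would also give unequal changes. Of the 32 genes, 27 were called lower and 2 higher in number libraries. Length and GC content of transcripts as the whole cause are argued against by the 14% of variance they explained over 8852 genes. RNA of other cells in the number libraries may contribute. The astrocyte, oligodendrocyte lineage, microglial and endothelial and mural lists all had medians of 2.1 or more (number minus letter). The last of these rests on Col1a1, Col1a2, Dcn and Pdgfrb, with no endothelial gene measured. Apoe was at 4940 CPM, Csf1r at 761, Olig1 at 476 and Col1a1 at 60.7 in number CPNSL libraries. In letter ones they were at 80.6, 24.5, 5.81 and 1.94. The tissue holds all of these cell types, and no step that would remove them is given in the sources used here. A difference of library batch or labelling stays open as well, untested. Read counting seems to differ for part of the 35 genes at 0 reads in all 5 letter libraries. Among them mt-Co3, mt-Atp6 and mt-Co2 had means of 4942.7, 4521.8 and 2435.0 CPM in number libraries. The 8 mitochondrially encoded genes outside these 35 had a median of 1.36 (log2 number minus letter). Whether counting differs for other genes was not tested.

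SSN b and c were closer to each other than other replicates. A single library sequenced or listed a second time would give a mean chi-square per gene near 1, and the value was 2.25, which argues against it. The 15 other pairs of 1 group and series had 24.8 to 92.6, and the lowest is 11 times that of b and c, so libraries made from shared RNA or cDNA may be the source. Animals that resemble each other more than other replicates do stay open and were not tested.

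Genes of non-neuronal cells differed between CPNSL and CPNDL in both directions, 8 of them on the 4 lists of such cells. A lower share of labelled neurons in one group, as the whole cause, would move all 4 lists to one side. Their medians lay on both sides of 0 and 2.05 apart, which argues against that. Only the endothelial and mural list was above 0 (1.52), with Col1a1, Col1a2, Dcn and Pdgfrb as its 4 measured genes. Those of the oligodendrocyte lineage, astrocytes and microglia were below it (-0.54, -0.17 and -0.09). A lower share in CPNDL together with a different mix of other cells is therefore not excluded. The 8 genes were 7.98 to 60.7 times higher in number than in letter CPNSL libraries (median 45.3), with Col1a1 at 60.7 CPM in CPNSL and Enpp6 at 63.8 CPM in CPNDL of the number series, so RNA of other cells that differ between superficial and deep tissue may explain them. Expression of these genes by the callosal neurons, and a difference of depth in how the cells were separated, stay open and were not tested.

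Other splits of the libraries were counted for each comparison. For SSN against CPNSL the 10 splits of the letter libraries are too few for a share under 0.05, with 944 genes in the real split and 213 in the highest other. For CPNSL against CPNDL only the real split, 1 of 35, gave as many as 429 genes. That share of 0.0286 is under 0.05 but is the smallest that 35 splits can give, so chance is argued against and not excluded. The highest other split gave 374 genes. That other split set CPNSL 1 and 3 with CPNDL 2 and 3 against the rest, as does the sign of the leading component of the residuals (51.4% of the residual variance of number libraries), so the libraries have a structure besides their group. For SSN against CPNDL, over their 7 libraries without a series term, the splits fall from 35 to 15 when SSN b and c count as 1, too few for a share under 0.05. The real split gave 1759 genes and the highest other of the 35 gave 113, and the real split is also the split by name series.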

How the results depend on the processing

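In this part the alternatives with a pseudocount of 1, SSN b and c averaged, the residual component, 50 CPM, genes at least as high in letter libraries, and unshifted values were chosen after seeing the data. The counts of genes reported above were 944 for SSN against CPNSL, 429 for CPNSL against CPNDL, 542 for SSN against CPNDL, 401 for SSN against both callosal groups, 116 for CPNDL against both others and 7027 for letter against number CPNSL libraries, and are given in this order below.

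Counts within 1.5 times these came from the replicate block (913, 474, 527, 369 and 143), median-of-ratios scaling (943, 415, 563, 426 and 120), a pseudocount of 1 (1117, 395, 671, 528 and 112) and a stricter filter, which removed 1 gene and so says little. The correlations of same-numbered residuals were -0.42, -0.39, 0.26 and 0.27. They cannot settle whether replicate numbers pair the libraries, since 1 component holds 51.4% of the residual variance of number libraries. Scaling moved the median change of all genes from -0.047 to 0.007 for SSN against CPNSL.

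Without the name-series term the counts were 2108, 834, 2364, 1449 and 425. With only the libraries of the compared series they were 1569, 219 and 1759, and 911 for SSN against both. Voom with quality weights gave 2969, 339, 1211, 1083 and 109, with weights of 5.25 and 6.84 for SSN b and c and 0.42 for SSN a. The deposited shift makes the letter and number CPNSL means equal. The fit without the name-series term, and that of SSN against CPNDL on their own libraries, therefore leave out the error of this shift. Their higher counts are no added support. For voom and the other fits on the compared series the cause was not tested. With SSN b and c averaged, which leaves 1 library fewer, the counts were 506, 315, 262, 197 and 58. Without SSN a, which also leaves 1 library fewer, they were 985, 432, 615, 501 and 108. The residual component as a covariate gave 1114, 612, 749, 520 and 192. It is built from residuals, so it left the changes as they were and altered only their errors, and says nothing on whether the component explains them. With fewer genes tested the counts were 525, 231, 289, 209, 61 and 3322 for the 4179 genes with a mean of at least 50 CPM, and 549, 252, 302, 229 and 60 for the 4663 genes at least as high in letter as in number CPNSL libraries.

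Leaving out each library in turn gave 296 to 1143 genes for SSN against CPNSL (296 without CPNSL e), 233 to 517 for CPNSL against CPNDL (233 without CPNSL 3), and 148 to 615 for SSN against CPNDL (148 without CPNSL e). For SSN against both it gave 111 to 501, for CPNDL against both 38 to 158, and for letter against number libraries 6279 to 7118. Without CPNSL d or e the lone letter CPNSL library is assumed to vary like the other groups.

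Camera called 11, 11 and 13 gene lists in the 3 comparisons and fry 10, 11 and 9, of which 5, 10 and 8 were called by both. Camera gave 0, 1 and 1 with a correlation estimated for each list. Leaving out 1 library gave 7 to 15 lists for SSN against CPNSL, with 7 without SSN b. The estimated correlation allows for genes of a list that move together, and the cause was not tested further.

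On unshifted values without the name-series term the counts were 3929, 61, 6474, 3758 and 44, because the difference between the series then enters SSN against the other groups and the spread within CPNSL. This setting reversed genes examined by name that were called in the report or only here (Hsp90aa1 and Pdgfrb, and Dlx1 for SSN against CPNDL). For SSN against CPNSL they were Pou3f2 (0.95), Dkk3 (-0.28), Nefm (0.7) and Rps12 (0.21). For CPNSL against CPNDL they were Limch1 (-0.07), Epha7 (0.12), Grm2 (0.2), Sh3gl2 (0.01), Slc17a7 (0.24), Nefm (0.02) and Dlx1 (-0.15). For SSN against CPNDL they were Ccdc80 (-0.7), Kcnip3 (-0.65), Dkk3 (-0.58), Limch1 (-0.81), Sema4g (0.45), Slit3 (0.03), Gria3 (0.28), Nefm (0.72), Hsp90aa1 (1.16), Dlx1 (-1.36), Dcn (-0.22), Col1a1 (-0.28), Col1a2 (-1.29) and Pdgfrb (-1.42). No gene examined by name that was called in the report or under the alternative reversed in the other alternatives given here. Of the 129, 126 and 126 named results in the 3 comparisons, calls were lost in 12, 7 and 16 with SSN b and c averaged, 11, 16 and 0 with only the compared series, 0, 11 and 11 with voom, 3, 1 and 6 with the replicate block, 3, 3 and 2 with median-of-ratios scaling and 1, 5 and 4 with a pseudocount of 1. On unshifted values 14, 42 and 12 were lost. Leaving out 1 library lost at most 22 (without CPNSL e), 16 (without CPNSL 4) and 38 (without CPNSL e).

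The count model written before the data were examined and its alternative count tool were not run, because the deposited unit is a log10 value. The recovered whole reads would have allowed them, so this was a choice. The fit without a filter was not run, because the genes were listed above a level. Depth limits genes below 0.093 to 0.205 CPM (3 reads), and changes near or below 10 CPM are understated by the scale.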

Other observations

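The genes in this part were chosen after their values were seen.

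Genes with CPNSL above both other groups, with the log2 change from CPNSL to SSN and then from CPNDL to CPNSL, were Npnt (-1.91 and 1.29), the oxytocin receptor Oxtr (-1.15 and 1.15), Tnc (-0.92 and 0.73), Kcnf1 (-0.91 and 0.66), neuroglobin, Ngb (-0.79 and 1.06), Cacng3 (-0.59 and 0.97) and Cntnap2 (-0.53 and 0.77). Genes with CPNSL below both were Chgb (0.88 and -0.45), the histamine receptor Hrh3 (0.81 and -0.57), the adenosine receptor Adora1 (0.7 and -0.43) and Foxp1 (0.5 and -0.6). Lypd6 was lowest in SSN and highest in CPNDL (-1.21 and -0.73), and Col6a1 (1.07 and 0.7) and Ccdc80 (1.24 and 0.65) were highest in SSN and lowest in CPNDL.

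The 35 genes listed at 0 reads in all 5 letter libraries included the mitochondrial genes mt-Co3, mt-Atp6 and mt-Co2, with means of 4942.7, 4521.8 and 2435.0 CPM over the number libraries, and Gm28437, Gm10925 and Gm28661 with 4966.1, 4472.1 and 2415.1. These zeros were not read as a level of expression. Of the genes called between CPNSL and CPNDL, 3.6% of the 279 higher in CPNSL and 8.7% of the 150 higher in CPNDL were at least 4-fold higher in number than in letter CPNSL libraries, against 5.7% of all 9019. At least as high in letter as in number CPNSL libraries were 69.9% of the 279, 38.7% of the 150 and 51.7% of all.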
